A study of Mus musculus with 22 samples.

How the data were processed

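RNA was measured in mouse cortex by poly(A)-selected, stranded paired-end sequencing, with a DNase digestion during extraction per the labels. At 6 months there were 12 libraries, 3 each of wild type (WT), N40K, 5xFAD and dTg mice, all littermates of crosses between N40K and 5xFAD carriers. N40K mice carry a transgene for an N-terminal fragment of U1-70K, a protein of the U1 small nuclear ribonucleoprotein (snRNP) that recognises 5′ splice sites. The 5xFAD mouse carries transgenes that lead to amyloid deposits, and dTg mice carry both sets of transgenes. At 12 months there were 10 libraries, 4 of WT mice and 6 of Tau P301S mice, which carry a mutant human tau transgene.

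The values analysed were the deposited Sd scores, a linear ratio per gene and library that the authors rounded to 3 decimals, taken here to be a splicing deficiency score in which a higher value stands for more unspliced signal. The submitters named CASAVA, STAR, BWA and bedtools 2.16.1 with the mm9 genome build. The formula of the score, the read counter, the annotation and the read depth per library were not given in the sources used here, so the depth behind each score is unknown and no interval that needs it is given. Expression levels were not analysed here, so a changed score says nothing of how much transcript was present. The scores were not checked against expected transgene expression for the same reason. Gene positions are not printed, because the reference annotation used here (GENCODE M21) is on another build than the scores. It served only to sum each gene's intron length by Ensembl identifier. The 12-month table identifies genes by symbol alone.

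The 6-month table held 15705 genes and the 12-month one 15192, with no missing value, so the alternatives for missing values had nothing to act on. Scores were put on a log2 scale after adding 0.002, the 5th percentile of the values above 0 in each table. All changes and folds below include this pseudocount, which draws the folds of the lowest scores towards 1. Libraries were not recentred, because a shift of all genes is a possible outcome of a splicing defect. Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), with 1 term per group and all libraries of a table in 1 fit. Each fit left 8 residual degrees of freedom, and the prior degrees of freedom were 1.2 at 6 months and 1.11 at 12 months, so genes borrowed little information on spread from each other. A gene passed at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes of the table. The 6-month contrasts were N40K minus WT, 5xFAD minus WT, dTg minus WT, dTg minus 5xFAD, dTg minus N40K, the N40K effect averaged over 5xFAD status and the interaction of both transgenes. The 5xFAD effect averaged over N40K status was added after the data had been examined.

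The median score of each library was compared between groups on the log2 scale by two-sided exact permutation tests, with the other transgene as a stratum for the averaged contrasts. Correlations of changes across genes are Pearson's r and Spearman's rho. Genes are not independent replicates, so these were set against the same value for other groupings of the libraries.

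Gene lists written before the data were examined were tested with camera (limma), with the preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the 15 lists of a comparison. Camera compares the members of a list with all other genes, so a list whose members change less than the general shift is called lower even where its own median is above 0. The lists were transgene-related genes, U1 snRNP and core spliceosome, SR proteins with CLK kinases and hnRNPs, glutamatergic synapse, GABAergic synapse and interneurons, synaptic vesicle release, voltage-gated ion channels, microglia including the amyloid-associated state, astrocytes, oligodendrocytes, endothelial cells and pericytes, Alzheimer disease risk and processing genes, immediate early genes, mitochondrial respiratory chain, and cytosolic ribosomal proteins. Lists of interferon-response genes and zinc-finger genes were added later.

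Named genes followed a rule written before the data were examined. It took up to 6 rises and 6 falls, the largest among genes past the threshold whose libraries did not overlap between the groups compared. It then took up to 3 members of each list past the threshold, or the member with the smallest p where none passed, and 6 transgene-related genes. Predicted genes (names in Gm with digits or ending in Rik) were counted and not named. The rule was written for 5 comparisons and extended after the data had been examined to the averaged contrasts, dTg minus N40K and the interaction. Any other gene named is said to have been chosen after its values were seen.

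Alternatives fixed before the data were examined were median-centring of each library, eBayes with a trend, leaving out the lowest 25 percent of genes by mean score, pseudocounts at the 1st and 25th percentiles (0.001 and 0.011 at 6 months, 0.001 and 0.006 at 12 months), the replicate number as a block, a fit of only the 2 groups compared, and leaving out each library in turn. Added after the data had been examined were a minimum mean score of 0.02, 20 seeded redraws of every score within 0.0005 either side of it, and leaving out both libraries with the highest medians. Where leaving out a library left few samples in a group, limma's pooled spread was used. The labels number the replicates and do not say that they are separate animals beyond being separate samples. If they are, the p-values measure variation between mice, and otherwise only variation between samples.

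The tests were tried on simulated scores in which 200 genes had been changed. N40K minus WT recovered 29% of changes of 0.5 (log2) and 77% of changes of 1. The averaged N40K contrast recovered 63% and 86%, and Tau P301S minus WT 19% and 73%. False calls were 8 of 114, 16 of 165 and 15 of 107, above the nominal share of 5% in each. The simulated noise was independent between genes and libraries, with no shift of a whole library. Where real libraries shift as a whole, false calls could be more frequent than in the simulation. Intron lengths were summed and figures drawn with Python 3.11.15 and matplotlib 3.10.9.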

Results

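Splicing deficiency scores (Sd scores, a ratio per gene) were compared in mouse cortex across 22 libraries. The 6-month libraries covered 15705 genes in WT, N40K, 5xFAD and dTg mice (n = 3 each), and the 12-month libraries covered 15192 genes in WT (n = 4) and Tau P301S mice (n = 6). The series asks, by its title, how a defect of the U1 snRNP linked to Alzheimer disease acts in these animals. Many scores were low: the mean score lay under 0.02 in 6065 genes (38.6%) at 6 months and in 8673 genes (57.1%) at 12 months. Below 0.02, 1 step of the last decimal is a sizeable part of the value. Libraries of the same table correlated across genes with r from 0.98 to 0.99 at 6 months (66 pairs) and from 0.949 to 0.986 at 12 months (45 pairs).

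The first question was whether the score shifted over all genes together. The median score per library was 0.033 ± 0.00265 in N40K and 0.0327 ± 0.00252 in dTg mice, against 0.0293 ± 0.000577 in WT and 0.03 ± 0.001 in 5xFAD mice (SD, n = 3 each). Averaged over 5xFAD status, N40K carriers stood 0.14 higher on the log2 scale (1.1-fold; exact permutation p = 0.02, 400 regroupings). N40K replicate 1 (0.036) and dTg replicate 2 (0.035) had the highest medians, and N40K replicate 2 (0.031) and dTg replicate 1 (0.03) lay within the range of the non-carriers (0.029 to 0.031). The corresponding 5xFAD difference was 0.01 (exact permutation p = 0.82), and its sign turned to −0.01 without N40K replicate 2 and to −0.02 without dTg replicate 2. It also fell below 0 without N40K replicate 3 (−0.00159) and without 5xFAD replicate 1 (−0.00302). Between single groups of 3, where the smallest exact p is 0.1, the difference was 0.16 for N40K minus WT (exact p = 0.1), 0.14 for dTg minus WT (exact p = 0.2) and 0.11 for dTg minus 5xFAD (exact p = 0.3). It was 0.03 for 5xFAD minus WT (exact p = 0.7) and −0.01 for dTg minus N40K (exact p = 0.9).

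**Figure D1:**
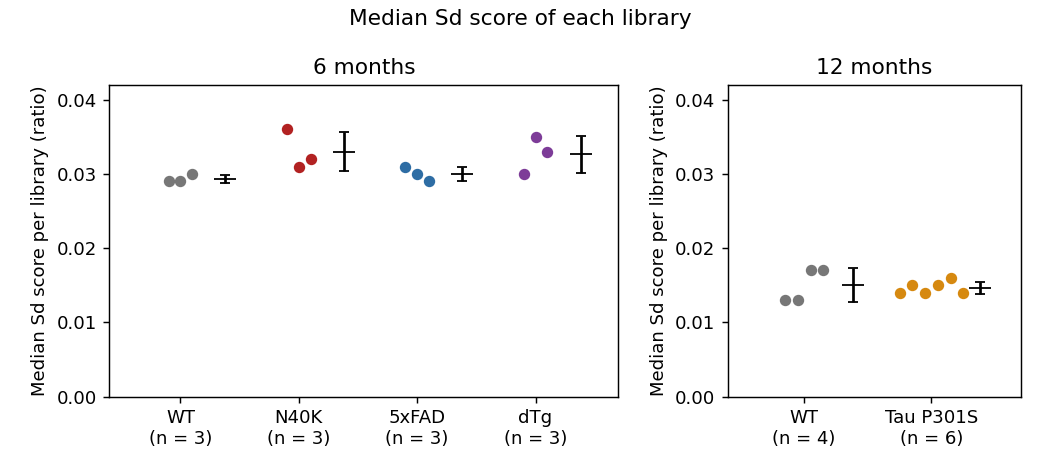
Median Sd score (ratio) of each library over all genes, by group, at 6 months (left, n = 3 per group) and 12 months (right, n = 4 and 6); points are libraries, and the bar beside them is the group mean ± SD. At 6 months the N40K and dTg means (0.033 and 0.0327) lie above those of WT and 5xFAD (0.0293 and 0.03), with 1 N40K library at 0.031 and 1 dTg library at 0.03, within the range of WT and 5xFAD libraries.

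The N40K effect averaged over 5xFAD status asks which genes differed between the 6 libraries with the transgene and the 6 without. It is a mean of both backgrounds, so a gene could pass on a change in 1 of them. The largest rises were in Ccdc24 (ENSMUSG00000078588), from 0.0285 ± 0.00855 to 0.103 ± 0.0268 (SD, n = 6 each, 3.42-fold, adjusted p = 0.00601), and in Lrrc8c (3.04-fold, adjusted p = 0.00861), a subunit of volume-regulated anion channels. Angptl2, which encodes a secreted angiopoietin-like protein, rose 3.01-fold, Cpped1 2.95-fold, Fam53b 2.84-fold and Kcnk3, a background potassium channel, 2.77-fold. Peg3 (ENSMUSG00000002265), an imprinted zinc-finger gene, fell from 0.131 ± 0.00695 to 0.0712 ± 0.0102 (0.545-fold, adjusted p = 0.00261). Vwa3b (0.402-fold), the zinc-finger gene Zfp930 (0.561-fold), the egg-coat gene Zp2 (0.623-fold), Mob3c (0.631-fold) and Ankrd39 (0.661-fold) fell as well. All 12 of these genes were separated between the 6 carrier and the 6 other libraries, as the naming rule required. In each of the 6 that rose, N40K replicate 1 and dTg replicate 2, the libraries of highest median, were the highest of their groups, as in Kcnk3 (0.102 and 0.097, against 0.045 to 0.058 in the other carriers). Without both, the 6 rises ranged from 1.15 to 1.6 on the log2 scale, against 1.47 to 1.77 with them, and each passed. Of the 6 that fell, Peg3 and Zfp930 passed without both as well, while Vwa3b (adjusted p = 0.12), Zp2 (0.101), Mob3c (0.0607) and Ankrd39 (0.0589) did not. Vwa3b and Zp2 also missed the threshold when 1 library was left out, in 10 and 9 of 12 cases, at adjusted p of up to 0.11 (without dTg replicate 2) and 0.0724 (without WT replicate 2), and Mob3c without 5xFAD replicate 3 (0.0502).

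In total 1691 genes rose and 147 fell (limma, adjusted p under 0.05; 1838 of 15705 genes), with a median change of 0.09 over all genes. The general shift weighed on this split: 92% of the genes that passed were higher, and 57.5% after each library had been centred on its own median (713 higher, 528 lower). A mean score of at least 0.02 left 832 genes, and redrawing the rounding left a median of 1637.5, with 1519 of the 1838 genes called in most draws. The count fell to 813 without WT replicate 2, 832 without 5xFAD replicate 3, 947 without dTg replicate 2, 965 without WT replicate 1, 1058 without N40K replicate 1 and 1173 without 5xFAD replicate 1. It was 749 without both libraries of highest median, of which 728 were among the 1838. Without both, the median change over all genes was 0.0525.

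Genes for the splicing machinery were among those whose scores changed with N40K. Of 31 SR proteins, CLK kinases and hnRNPs, 4 rose and none fell (11 rose adjusted over the list alone). Hnrnpu (ENSMUSG00000039630), an RNA-binding nuclear matrix protein, went from 0.112 ± 0.00295 to 0.14 ± 0.00418 (SD, n = 6 each, 1.25-fold, adjusted p = 0.002), with Srsf11 at 1.31-fold and Srsf1 at 1.25-fold. Srsf1 missed the threshold in 5 of 12 cases of 1 library left out (adjusted p up to 0.0633, without WT replicate 2) and without both libraries of highest median (0.108). Of 28 U1 snRNP and core spliceosome genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone). The U1-associated genes Luc7l2 (1.4-fold, adjusted p = 0.0125) and Luc7l3 (1.27-fold, adjusted p = 0.0125) rose, and Sf3b3, of the SF3b complex, fell (0.853-fold, adjusted p = 0.0125). Relative to the median of all genes, the list medians lay at 0.02 and −0.03, and camera separated neither list from the other genes (adjusted p = 0.227 and 0.656). Snrnp70, the mouse gene for U1-70K, had 0.0415 ± 0.00207 with the transgene and 0.0447 ± 0.000816 without (adjusted p = 0.0935), and none of the 6 transgene-related genes passed (limma; 3 at an unadjusted p under 0.05, camera adjusted p = 0.475).

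Neuronal genes were tested in 4 lists. Of 41 voltage-gated ion channel genes 8 rose and none fell (12 adjusted over the list alone), among them the potassium channel genes Kcna1, from 0.055 ± 0.00921 to 0.0965 ± 0.0125 (1.74-fold, adjusted p = 0.0102) and Kcnc2 (1.22-fold). Kcnab1, also among the 8, stood at 0.001 in all WT libraries and at 0.002 in all others, so it differed with N40K in mice without 5xFAD transgenes but not between dTg and 5xFAD mice. The list median lay 0.07 above that of all genes (camera adjusted p = 0.0131, adjusted p = 0.712 with an estimated correlation). Of 33 synaptic vesicle release genes 5 rose (7 adjusted over the list alone), including Vamp1 (1.48-fold) and Snap25 (1.36-fold), SNARE proteins of vesicle fusion, and the active-zone gene Rims2 (0.001 to 0.002 in all libraries). Of 31 glutamatergic genes 3 rose and 1 fell (6 and 1 adjusted over the list alone), with the NMDA receptor subunit Grin1 at 0.899-fold. Grin1 (adjusted p = 0.0464) missed the threshold in 10 of 12 cases of 1 library left out (up to 0.104, without dTg replicate 2). Without both libraries of highest median it missed it as well (0.0558). Of 32 GABAergic genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Slc12a2, a chloride importer, at 1.51-fold and the receptor subunit Gabra2 at 1.37-fold (adjusted p = 0.0541 without both libraries of highest median). In these last 2 lists the share of genes that rose was below that over all genes (1691 of 15705). Camera gave adjusted p = 0.227 for vesicle release, 0.341 for the glutamatergic and 0.518 for the GABAergic list.

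Other cell types and housekeeping groups were tested with the remaining lists. Among 22 astrocyte genes S100b (1.2-fold) and the glutamate transporter Slc1a2 (1.13-fold) rose and the transcription factor Sox9 (0.682-fold) was lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.0518). Sox9 had 0.0247 in WT and 0.024 in N40K mice against 0.0467 in 5xFAD and 0.022 in dTg mice, so its averaged difference came mostly from dTg against 5xFAD (interaction −0.96, limma unadjusted p = 0.0101, adjusted p = 1). The median change of the astrocyte list was above 0 (0.00169) and its mean below (−0.00647). The oligodendrocyte list (15 genes) had a lower averaged score of Olig2 (0.815-fold; none adjusted over the list alone, camera adjusted p = 0.518). Olig2 had 0.131 in WT and 0.122 in N40K mice, whose libraries overlapped, against 0.175 in 5xFAD and 0.124 in dTg mice (interaction −0.38, limma unadjusted p = 0.0419, adjusted p = 1). The endothelial and pericyte list (13 genes) had a fall of Tek, an angiopoietin receptor (0.796-fold; 1 adjusted over the list alone). The median of the endothelial list lay at −0.155 relative to all genes (camera adjusted p = 0.000623, adjusted p = 0.39 with an estimated correlation). Bdnf rose 1.68-fold among 14 immediate early genes (1 adjusted over the list alone), while this list as a whole lay lower (camera adjusted p = 0.0232, adjusted p = 0.539 with an estimated correlation). Of 36 respiratory chain genes Atp5c1 (1.23-fold) and Ndufv1 (1.27-fold) rose (1 adjusted over the list alone, camera adjusted p = 0.138). None of 41 ribosomal protein genes passed (limma; 2 at an unadjusted p under 0.05), and the list lay lower than other genes (camera adjusted p = 0.000567, adjusted p = 0.39 with an estimated correlation). None of 25 microglial genes passed either (2 unadjusted, camera lower, adjusted p = 0.0286, adjusted p = 0.447 with an estimated correlation), nor of 26 Alzheimer disease risk genes (3 unadjusted, camera adjusted p = 0.225).

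Several of the genes named from these last lists missed the threshold when 1 of the 12 libraries was left out. This held for Olig2 in 11 cases (adjusted p up to 0.0926, without 5xFAD replicate 3), Sox9 in 10 (up to 0.1, without WT replicate 2), Slc1a2 in 9 (up to 0.0821, without 5xFAD replicate 3), Ndufv1 in 9 (up to 0.0868, without dTg replicate 2) and Bdnf in 5 (up to 0.0602, without dTg replicate 2). Without both libraries of highest median Olig2 (0.159), Ndufv1 (0.133), Sox9 (0.107), S100b (0.0665) and Atp5c1 (0.0542) missed it.

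**Figure D2:**
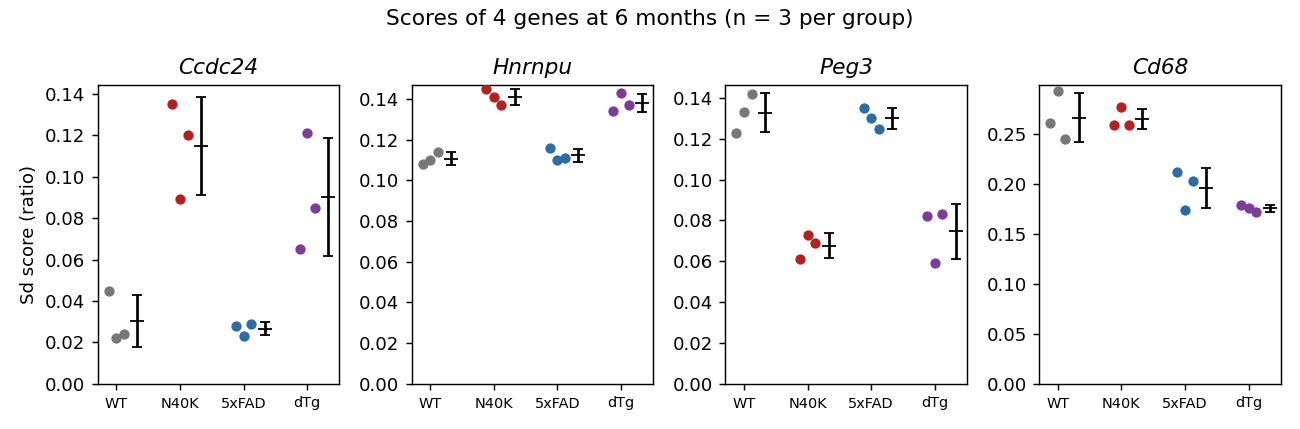
Sd score (ratio) of Ccdc24, Hnrnpu, Peg3 and Cd68 in each 6-month library by group (n = 3 per group); points are libraries and bars the mean ± SD. Ccdc24 and Hnrnpu were higher and Peg3 lower in N40K and dTg libraries than in WT and 5xFAD libraries, while Cd68 was lower in 5xFAD and dTg libraries (0.196 and 0.176 against 0.266 and 0.265); the genes were picked for display after their values had been seen.

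N40K minus WT asks for the effect of the transgene without amyloid transgenes. The axon-guidance gene Slit3 rose from 0.002 in all WT libraries to 0.00567 ± 0.00115 (SD, n = 3, 1.9-fold, adjusted p = 0.0336), and Slc38a9, a lysosomal amino acid transporter, rose from 0.021 ± 0.003 to 0.0363 ± 0.00153 (1.68-fold, adjusted p = 0.0225). Fam196a (1.89-fold), RP23-393F23.8 (1.76-fold), the ciliary gene Evc (1.59-fold) and the protocadherin Pcdh10 (1.52-fold) rose as well. Peg3 (0.517-fold), Nudt16 (0.597-fold), the formin-binding gene Fnbp4 (0.682-fold) and Praf2 (0.721-fold) fell. Hnrnpu (1.27-fold, 1 of 31 in its list, 3 adjusted over the list alone), Rims2 (1 of 33, 3 adjusted over the list alone) and Kcnab1 (1 of 41, 4 adjusted over the list alone) passed among the lists. The endothelial list (camera adjusted p = 0.0105, adjusted p = 0.734 with an estimated correlation) and the ribosomal list (camera adjusted p = 0.0191, adjusted p = 0.734 with an estimated correlation) lay lower than other genes. In all 24 genes rose and 4 fell (limma; 2967 at an unadjusted p under 0.05), and 13 of the 28 had no spread within any group. Of the 13 genes named here, RP23-393F23.8, Fnbp4, Rims2 and Kcnab1 passed without each single library of either group. Each of the other 9 missed the threshold without at least 1 of these libraries (adjusted p up to 0.16). Rims2 and Kcnab1 stood at 0.001 in all WT and at 0.002 in all N40K libraries, so no omission could change their difference. None passed after centring (0 genes; 3019 unadjusted), none of the 28 was called in most redraws of the rounding, 18 genes passed without WT replicate 1 and 18 without N40K replicate 1, and 254 without both libraries of highest median.

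dTg minus 5xFAD asks for the effect of N40K in mice with amyloid transgenes. Cdk8, a kinase of the Mediator complex, rose from 0.0477 ± 0.000577 to 0.0927 ± 0.0131 (SD, n = 3 each, 1.89-fold, adjusted p = 0.0247), and Slit3 (1.86-fold), B3galt1 (1.66-fold), the cation channel gene Trpc5 (1.65-fold), Rnf217 (1.65-fold) and RP23-393F23.8 (1.6-fold) rose as well. Peg3 fell from 0.13 ± 0.005 to 0.0747 ± 0.0136 (0.574-fold, adjusted p = 0.0459), as did Ccdc46 (0.696-fold), Fnbp4 (0.752-fold), Snrnp48, a protein of the minor spliceosome (0.765-fold), and the tubulin gene Tuba1a (0.857-fold). Within the lists Hnrnpu (1.22-fold, 1 of 31, 2 adjusted over the list alone), Slc12a2 (1.56-fold, 1 of 32, 1 adjusted over the list alone), Rims2 and Snap25 (2 of 33, 3 adjusted over the list alone) rose. Camera placed ribosomal (adjusted p = 0.000401), endothelial (0.00319), microglial (0.0132), astrocyte (0.0239) and immediate early genes (0.0239) lower and voltage-gated channels higher (0.0239) than other genes; with an estimated correlation none of the 6 passed, at adjusted p = 0.377, 0.377, 0.377, 0.518, 0.556 and 0.845. In all 44 genes rose and 5 fell (limma, 2834 at an unadjusted p under 0.05). Among these calls 14 differed by at most 1 step of the last decimal, as did Tuba1a (0.005 in all 5xFAD and 0.004 in all dTg libraries). With those left out of the adjustment, none of the other calls passed. Of the 15 genes named here, Rims2 passed without each single library of either group. Each of the other 14 missed the threshold without at least 1 of these libraries (adjusted p up to 0.173). Rims2 stood at 0.001 in all 5xFAD and at 0.002 in all dTg libraries, so no omission could change its difference. None passed after centring (0 genes; 2534 unadjusted), none was called in most redraws, and the count was 19, 30 and 18 without 5xFAD replicates 1, 2 and 3, 80 without dTg replicate 1 and 170 without both libraries of highest median.

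dTg minus WT takes both sets of transgenes together. Loxl4, of the lysyl oxidase family, rose from 0.186 ± 0.056 to 0.635 ± 0.0878 (SD, n = 3 each, 3.48-fold, adjusted p = 0.0248), followed by Iqcj (3.2-fold), Nmnat1, a nuclear NAD-synthesising enzyme (3.19-fold), Ccdc24 (2.9-fold), Fgf17 (2.63-fold) and Atxn1 (2.61-fold). Cd180, a Toll-like receptor homologue, fell from 0.498 ± 0.0384 to 0.217 ± 0.0186 (0.439-fold, adjusted p = 0.0363), with Usp18, a deconjugase of the interferon-induced modifier ISG15 (0.507-fold), Spag4 (0.527-fold), Zfp930 (0.553-fold), Peg3 (0.564-fold) and the microglial lysosomal gene Cd68 (0.664-fold, adjusted p = 0.0248). Of 25 microglial genes 3 fell, Cd68, Grn (0.857-fold) and Ctsz (0.698-fold), and 5 adjusted over the list alone (camera adjusted p = 3.75e-10, adjusted p = 0.0163 with an estimated correlation). Grn also belongs to the 26 Alzheimer risk genes, where it alone fell (1 adjusted over the list alone). Vamp1 (1.67-fold), Snap25 (1.46-fold) and Rims2 rose among 33 vesicle genes (4 adjusted over the list alone), Slc12a2 among 32 GABAergic genes (4 adjusted over the list alone), Hnrnpu among 31 SR and hnRNP genes (4 adjusted over the list alone) and Kcnab1 among 41 channel genes (11 adjusted over the list alone). Camera also called the channel list higher (adjusted p = 0.000217, adjusted p = 0.471 with an estimated correlation) and ribosomal (1.01e-05), astrocyte (0.0019), endothelial (0.0114) and Alzheimer risk genes (0.0216) lower, which ended at adjusted p = 0.147, 0.29, 0.471 and 0.471 with an estimated correlation. In all 221 genes rose and 26 fell (limma; 3533 at an unadjusted p under 0.05; 89.5% higher), and 163 passed after centring (60.1% higher, 98 and 65). Of the 20 genes named here, Rims2 and Kcnab1 passed without each single library of either group. Each of the other 18 missed the threshold without at least 1 of these libraries (adjusted p up to 0.153). Rims2 and Kcnab1 stood at 0.001 in all WT and at 0.002 in all dTg libraries, so no omission could change their difference. They were called in 4 and 6 of 20 redraws of the rounding. Of the microglial genes that fell, Cd68 was called in 20, Ctsz in 4 and Grn in 0 of the 20 redraws. The count was 30, 31 and 55 without WT replicates 1, 2 and 3 and 55 without dTg replicate 2, a minimum mean score of 0.02 left 49, and 123 of the 247 genes were called in most redraws of the rounding.

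**Figure D3:**
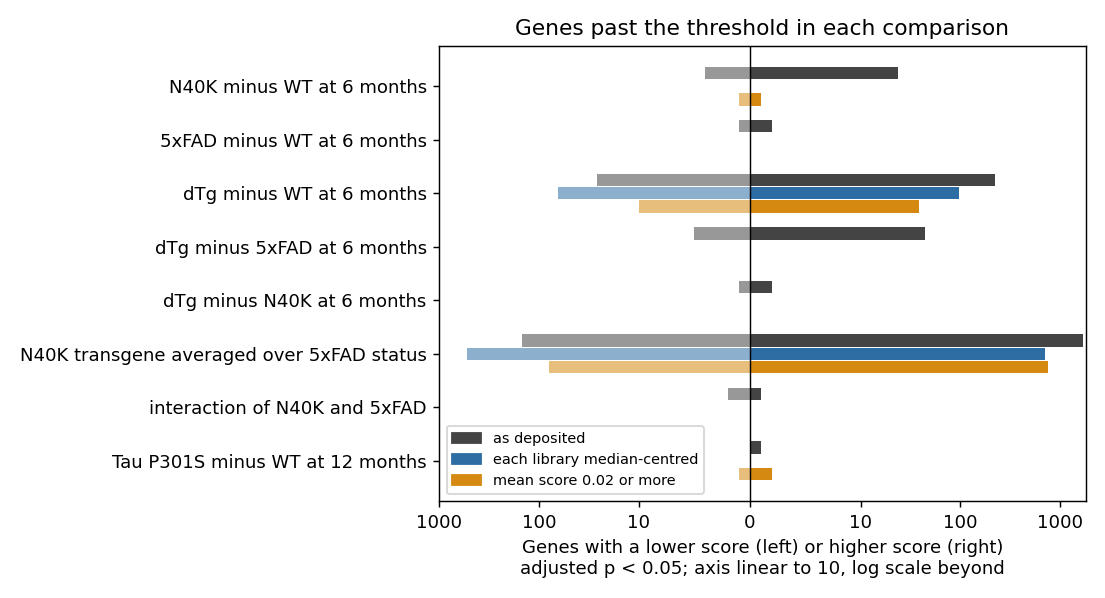
Number of genes with a lower (left) or higher (right) Sd score at an adjusted p under 0.05 in each comparison, for scores as deposited, after median-centring of each library and with a mean score of at least 0.02; the axis is linear up to 10 and logarithmic beyond. For averaged N40K the higher and lower counts were 1691 and 147 as deposited, 713 and 528 after centring, and 752 and 80 with the minimum.

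The interaction asks whether the N40K effect differed between mice with and without 5xFAD transgenes. Synpr, a synaptic vesicle protein gene, was listed at 0 in all libraries except dTg, at 0.001 (interaction 0.58, adjusted p = 0.0018). Atp2b2, a plasma-membrane calcium pump, and Kcnab1 stood at 0.001 in all WT libraries and at 0.002 in all others (interaction −0.42 each, adjusted p = 0.0119 each). No other gene passed (limma; 1 higher, 2 lower; 450 at an unadjusted p under 0.05), and camera passed none of the 15 lists. These 3 genes showed no spread in any group, and each was called in 0 of 20 redraws of the rounding. The count ranged from 1 without WT replicate 1 or N40K replicate 3 to 14 without N40K replicate 1, with 5, 9, 6, 5, 7, 5, 6 and 6 without WT replicates 2 and 3, N40K replicate 2, 5xFAD replicates 1, 2 and 3, and dTg replicates 2 and 3, and was 22 without both libraries of highest median.

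5xFAD minus WT asks for the effect of the amyloid transgenes alone. Atp2b2 and Kcnab1 rose (0.001 to 0.002, adjusted p = 0.000872 each) and Cst3, for the protease inhibitor cystatin C, fell (0.003 to 0.002, adjusted p = 0.00538), with no spread within groups and no call in any redraw. The microglial list lay lower (camera adjusted p = 5.09e-08, adjusted p = 0.034 with an estimated correlation): no member passed over all genes (limma; 6 at an unadjusted p under 0.05) and 5 fell adjusted over the list alone. Its member with the smallest p, Cd68, had 0.196 ± 0.0199 against 0.266 ± 0.0244 (SD, n = 3 each, adjusted p = 0.544). Sox9 had 0.0467 ± 0.00416 against 0.0247 ± 0.00289 (adjusted p = 0.682) and Olig2 0.175 ± 0.0107 against 0.131 ± 0.0139 (adjusted p = 0.747). App was listed at 0 in all libraries. In all 2 genes rose and 1 fell (limma; 690 at an unadjusted p under 0.05), with 8 and 12 genes without WT replicates 2 and 3, 7, 11 and 5 without 5xFAD replicates 1, 2 and 3, and 10 without both libraries of highest median.

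dTg minus N40K, the amyloid effect in N40K carriers, again had lower scores in the microglial list. Cd68 had 0.176 ± 0.00351 against 0.265 ± 0.0104 (SD, n = 3 each, adjusted p = 0.203), and the list lay lower (camera adjusted p = 4.46e-11, adjusted p = 0.0123 with an estimated correlation; 0 over all genes by limma, 8 at an unadjusted p under 0.05 and 6 adjusted over the list alone). Synpr (0 to 0.001, adjusted p = 8.08e-05) and Prex1 (0.002 to 0.003, adjusted p = 0.00538) rose and Cst3 fell (0.003 to 0.002, adjusted p = 0.00538). Camera called astrocytes (adjusted p = 0.00462) and ribosomal genes (0.0188) lower and voltage-gated channels (0.0188) and glutamatergic genes (0.019) higher; with an estimated correlation these were at adjusted p = 0.458, 0.648, 0.786 and 0.786. In all 2 genes rose and 1 fell (limma; 807 at an unadjusted p under 0.05), none called in any redraw. The count was 22 and 7 without N40K replicates 1 and 2, 5, 8 and 6 without dTg replicates 1, 2 and 3, and 34 without both libraries of highest median.

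Averaged over N40K status, 5xFAD carriers had lower scores of Cd68 (ENSMUSG00000018774) and Usp18. Cd68 fell from 0.266 ± 0.0168 to 0.186 ± 0.0171 (SD, n = 6 each, 0.701-fold, adjusted p = 0.0265; lower in 6 of 6 carrier libraries) and Usp18 from 0.0485 ± 0.00675 to 0.0238 ± 0.00271 (0.513-fold, adjusted p = 0.0248). Both missed the threshold in 7 of 12 cases of 1 library left out (adjusted p up to 0.0956 and 0.0841) and without both libraries of highest median (0.0716 and 0.0799). Cst3 fell as well, and Synpr, Atp2b2, Kcnab1 and Prex1 rose; these 5 had no spread within groups, and Synpr, Atp2b2 and Prex1 were named after their values had been seen. Of 25 microglial genes 1 fell over all genes and 9 adjusted over the list alone, and the list median was −0.185 (camera adjusted p = 2.48e-13, adjusted p = 0.00664 with an estimated correlation). Among the 9 were Cd68, Lgals3bp, Ctsz, Grn, Ctsd, P2ry12, Lpl and Spp1, named after their values had been seen. Voltage-gated channels (camera adjusted p = 0.00188) lay higher and astrocytes (0.00883), ribosomal genes (0.0205) and Alzheimer risk genes (0.0429) lower, at adjusted p = 0.65, 0.615, 0.65 and 0.65 with an estimated correlation. C4a, in the astrocyte list, had 0.227 ± 0.017 against 0.285 ± 0.0142 (adjusted p = 0.144). In all 4 genes rose and 3 fell (limma; 969 at an unadjusted p under 0.05), and after centring 1 gene was higher and 10 lower (57.1% higher before and 9.09% after). The count was 15 without WT replicate 3, 21 without N40K replicate 1, 20 and 13 without 5xFAD replicates 1 and 2, and 38 without both libraries of highest median.

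Tau P301S minus WT at 12 months asks for the effect of mutant tau. Astn1, a neuronal migration gene, was listed at 0 in all WT libraries and at 0.001 in all Tau P301S libraries (adjusted p = 0.000103), and no other of 15192 genes passed (limma; 1 higher, 0 lower; 1258 at an unadjusted p under 0.05). Mapt, the tau gene, had 0.00483 ± 0.000408 (SD, n = 6) against 0.00275 ± 0.000957 (n = 4, adjusted p = 0.302), and 2 of 6 transgene-related genes were higher adjusted over the list alone (camera adjusted p = 0.14). The vesicle gene Sv2c had 0.126 ± 0.0271 against 0.0622 ± 0.0147 (adjusted p = 0.291, 1 of 33 higher adjusted over the list alone), and Plcg2, an Alzheimer risk gene, 0.00333 ± 0.000516 against 0.00525 ± 0.0005 (adjusted p = 0.291; 1 higher and 1 lower of 27 adjusted over the list alone). The microglial list (32 genes, 0 past the threshold over all genes or adjusted over the list alone by limma, 9 at an unadjusted p under 0.05) lay lower (camera adjusted p = 0.00464, adjusted p = 0.961 with an estimated correlation). With a minimum mean score of 0.02, 3 genes passed at adjusted p = 0.048 each, AU040320 (0.0465 ± 0.00575 against 0.0253 ± 0.00299), Prnd (0.0362 ± 0.00553 against 0.0177 ± 0.00206) and Tnfaip8l2 (0.0245 ± 0.00873 against 0.0935 ± 0.021), chosen after their values had been seen. Astn1 was called in 0 of 20 redraws of the rounding, and 2, 5, 2, 3 and 4 genes passed without WT replicates 3 and 4 and Tau P301S replicates 1, 2 and 3. The median per library was 0.0147 ± 0.000816 (n = 6) against 0.015 ± 0.00231 (n = 4; log2 difference −0.02, exact permutation p = 0.829, 210 regroupings), and the sign turned to 0.04 without WT replicate 3 or 4.

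Changes were also compared between contrasts across genes. N40K minus WT and dTg minus 5xFAD, which share no library, had r = 0.511 and rho = 0.529 over 15705 genes, with the same sign in 70.9% of genes. Of all genes, 69.3% were higher in the first contrast and 69.7% in the second, so part of the shared sign follows from the general shift. Of the 10 splits tried, the real one included, the highest other gave an r of 0.335. 5xFAD minus WT and dTg minus N40K had r = 0.161 and rho = 0.135, against 0.114 for the highest other split. N40K minus WT and Tau P301S minus WT had r = 0.0864 and rho = 0.0899 over 12952 shared symbols, with the same sign in 49.8%. Of 100 regroupings of the 12-month libraries, the real one included, 11 gave an r as large in size, and the others ranged from −0.107 to 0.106. The first 2 of these 3 correlations were chosen after the data had been examined, and genes are not independent replicates.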

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

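Among the tests below, those of the rounding, of both libraries with the highest medians, of signal added to every gene and of the microglial subsets, as well as the averaged 5xFAD contrast, were chosen only after the results had been seen; the counts over other splits of the libraries were planned.

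The number of genes past the threshold with the N40K transgene, 1838 in both directions (1691 higher and 147 lower), was larger than in any other of 100 splits of the libraries within each 5xFAD status. Of these, 1 gave as many genes, the real one, and the highest other gave 6, so chance is made less likely for that count and is not excluded. The other splits mixed carriers with non-carriers within groups, so the N40K difference itself widened their spread and could lower their counts. Rounding of low scores is argued against as the whole cause of the general rise, since the median change was 0.075 in genes with a mean score of at least 0.02. N40K replicate 1 and dTg replicate 2 carried part of it: without both the median change over all genes was 0.0525, against 0.09 with them, which is barely above the bound of 0.05 set for excluding them as the whole cause. Intron signal added to every gene, as from genomic DNA or unspliced RNA carried over in some libraries, could raise scores in the same way and cannot be told apart from the transgene, because the 8% of calls that were falls lie between what it allows and what would exclude it, that bound having been set with the value known. An effect of the transgene on splicing, the contrast the design names, therefore stays open as a hypothesis, and the labels state a DNase digestion for all libraries without giving its outcome.

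Of the 28 calls in N40K minus WT, 15 lay in genes with a mean score under 0.02 and 13 in genes above that. None was made in most of 20 redraws within the last decimal, where redrawing adds noise of its own. Rounding of the deposited scores to 3 decimals can make at most 1 step of 0.001 between group means. Among the 15, 13 differed by 1 step with no spread in any group, so rounding and a real change cannot be told apart there, and 2 differed by more than a step. Among the 13 of higher score the smallest difference was 0.009, which argues against rounding as the source of these differences. Their median change in size was 0.592 ± 0.21 on the log2 scale (SD over 13 genes) as deposited and 0.595 in the redraws (range 0.566 to 0.625). Redraws within 0.0005 could hardly move changes of this size, so that likeness is no test of rounding. The calls of these 13 genes rested in part on the small p-values of the 1-step genes in the adjustment. Without those, 1 of the 13 passed. In dTg minus WT, 16 of 247 calls differed by at most 1 step, and 123 were kept in most redraws.

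Microglial genes were lower in 5xFAD carriers, with 9 of 25 past the threshold adjusted over the list alone. A larger share of microglia that affected all microglial genes alike cannot be told apart from a change within microglia: members of the amyloid-associated state lay −0.1 from the other members on the log2 scale (−0.26 ± 0.332, 14 genes, against −0.16 ± 0.176, 11 genes, SD), with a permutation p of 0.384. If the score relates unspliced to spliced signal, more spliced transcript per cell might lower it without a change in splicing. Expression levels were not analysed here, so this stays open and untested. The amyloid transgenes are the difference the design names, and 11 of 100 splits gave as many genes past the threshold as the averaged 5xFAD contrast (7, highest other 63), so chance cannot be excluded for that count; the list test was not run over other splits.

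Counts over other splits of the libraries were as follows for the remaining contrasts. With 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. The real split gave 28 genes in N40K minus WT (1 of 10 splits as large, highest other 4), 247 in dTg minus WT (1 of 10, highest other 3), 49 in dTg minus 5xFAD (1 of 10, highest other 4) and 3 in 5xFAD minus WT (4 of 10, highest other 4). In dTg minus N40K 7 of 10 splits gave as many as the real 3. The split that set N40K replicate 1 with dTg replicates 2 and 3 against the others gave 192. Those libraries had medians of 0.036, 0.035 and 0.033, against 0.031 and 0.032 in N40K replicates 2 and 3 and 0.03 in dTg replicate 1. That split thus followed the level of the library medians and not 5xFAD status, among mice that all carry N40K. For the interaction 14 of 100 splits gave at least the real 3 genes. The highest, 1814, was the split whose contrast set all N40K and dTg libraries against the rest. These splits moved libraries freely between the 4 groups, so the N40K difference itself entered them. Their share therefore cannot decide on the interaction, and chance stays possible. For Tau P301S minus WT 42 of 100 splits gave at least the real 1 gene, so chance cannot be excluded either. There the split that set WT replicates 1 and 2 with Tau P301S replicates 1 and 4 against the others gave 392, a structure of the samples that the groups do not name; the labels give no batch, so no blocked value can be had.

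At 12 months single libraries stood apart from their group in 7 of 39 tests of a gene or the median in 1 group, by their gap to the nearest other library. Chance would give 1.95 with unrounded values, which is no reference here: in 6 of the 7 all other libraries shared 1 rounded value, so that any gap had to stand out. The 6-month groups of 3 were not tested in this way. In WT mice at 12 months these were Shank3 (lowest 0.009, the others 0.01), Gad1 (lowest 0.004, the others 0.005), C4a (highest 0.231, the others 0.194 to 0.2) and Plcg2 (highest 0.006, the others 0.005). In Tau P301S mice they were Mapt (lowest 0.004, the others 0.005), Shank3 (lowest 0.008, the others 0.009) and Thy1 (highest 0.007, the others 0.006). In each case except C4a the gap was 1 step of the last decimal, 0.001.

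The effect of N40K differed between mice with and without 5xFAD transgenes in Synpr (0.585 on the log2 scale, adjusted p = 0.0018), Atp2b2 (−0.415, adjusted p = 0.0119) and Kcnab1 (−0.415, adjusted p = 0.0119) by limma's interaction term. Each rested on 1 step of the last decimal with no spread in any group, and none was called in any of 20 redraws.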

How the results depend on the processing

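The minimum mean score, the redrawn rounding, the omission of both libraries with the highest medians and every alternative of the averaged 5xFAD contrast were chosen after results had been seen; the other alternatives were planned. The averaged N40K count stayed at 749 genes or more under every alternative run, and its shared genes kept their direction, though the count moved. The counts between single groups moved further, several of them to 0. Of the values for single named genes under alternatives, 3259 were the same in direction and side of the threshold. Of the others, 522 were no longer past the threshold, 11 newly passed, 21 without a call changed sign and 0 calls reversed. Unless stated, the cause was not tested. Read depth is not known, so what it limits was not tested; the last decimal limits genes with scores near 0.001.

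Genes past the threshold are given in the order N40K minus WT, 5xFAD minus WT, dTg minus WT, dTg minus 5xFAD, dTg minus N40K, averaged N40K, interaction, averaged 5xFAD and Tau P301S minus WT, which had 28, 3, 247, 49, 3, 1838, 3, 7 and 1 genes. After median-centring they were 0, 0, 163, 0, 0, 1241, 0, 11 and 0 (limma; unadjusted counts for the zeros 3019, 738, 2534, 927, 588 and 1408), with 859 of the 1838 genes shared. Without the lowest 25 percent of genes they were 0, 0, 57, 0, 0, 1121, 0, 4 and 0 (unadjusted for the zeros 2048, 489, 1927, 545, 331 and 1028), and with a mean score of at least 0.02 they were 2, 0, 49, 0, 0, 832, 0, 1 and 3 (unadjusted for the zeros 398, 1512, 465 and 286), partly because fewer genes were tested. With the pseudocount at the 25th percentile the first 8 were 3, 0, 157, 0, 0, 1696, 0 and 0. Redrawn rounding gave medians of 0, 0, 161, 0, 0, 1637.5, 0, 4 and 0. Without both libraries of highest median the first 8 were 254, 10, 252, 170, 34, 749, 22 and 38. A fit of only the 2 groups compared gave 105 for N40K minus WT, 27 for 5xFAD minus WT, 156 for dTg minus WT and 0 for dTg minus N40K, and eBayes with a trend gave 5 for the interaction.

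Leaving out 1 library at a time gave 18 to 36 genes for N40K minus WT, 4 to 12 for 5xFAD minus WT, 30 to 223 for dTg minus WT, 18 to 80 for dTg minus 5xFAD, 4 to 22 for dTg minus N40K, 813 to 2352 for averaged N40K, 1 to 14 for the interaction, 5 to 21 for averaged 5xFAD and 1 to 5 for Tau P301S minus WT. A lone omission changes both the spread and the number of samples. The median per library stood 0.105 to 0.163 higher with N40K (exact p from 0.005 to 0.045). For averaged 5xFAD the difference ranged from −0.0159 to 0.0385 and was negative without N40K replicate 2 (−0.0124), N40K replicate 3 (−0.00159), 5xFAD replicate 1 (−0.00302) and dTg replicate 2 (−0.0159). For Tau P301S minus WT it ranged from −0.0768 to 0.0369, reached without WT replicate 3 (0.0369) or WT replicate 4 (0.0369).

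Equal replicate numbers were not taken to pair the samples. Over 18 pairs of libraries with the same number at 6 months the residuals correlated with r from −0.2 to 0.0708, none above 0.1. Over 4 pairs at 12 months r ran from −0.265 to 0.191, 1 above 0.1. Low correlations over so few pairs cannot exclude a batch shared by equal numbers, and the labels do not settle it. With the replicate block the counts were 17, 2, 31, 15, 1, 889, 0, 2 and 0 in the order above, with fewer residual degrees of freedom by construction, and 867 of the 1838 averaged N40K genes shared.

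Of the 15 gene lists, those past the threshold fell with an estimated inter-gene correlation from 2 to 0 in N40K minus WT, 6 to 1 in dTg minus WT, 6 to 0 in dTg minus 5xFAD, 5 to 1 in dTg minus N40K, 5 to 0 in averaged N40K, 5 to 1 in averaged 5xFAD and 1 to 0 in Tau P301S minus WT. The list that stayed was the microglial one. With a mean score of at least 0.02 they were 0, 2, 2, 2, 2, 3 and 0 in this order, and after centring 4 in N40K minus WT and 3 in averaged 5xFAD. Without both libraries of highest median they were 1 in N40K minus WT, 3 in dTg minus N40K and 3 in averaged N40K.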

Other observations

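The zinc-finger test was chosen only after the genes it concerns had been seen; the tests of interferon-response genes and of intron length were prompted by called genes, with their predictions set before their own values were computed.

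Interferon-response genes followed microglial genes in 5xFAD carriers. Of 40 such genes, chosen without those already seen, 29 were measured, and 23 of these had a negative change averaged over N40K status, with a median of −0.13. None passed over all genes (limma; 5 at an unadjusted p under 0.05) and 3 were lower adjusted over the list alone. Camera placed the list lower than other genes with p = 2.04e-06 (n = 29 genes), and with an estimated correlation p = 0.00413 (n = 29 genes), which is in line with the hypothesis that interferon-response genes fall as well. In Tau P301S mice 20 of 28 were negative (p = 0.00404, and 0.0837 with an estimated correlation, n = 28 genes).

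Genes with more intron sequence may have risen more with the N40K transgene. Across 14854 genes (94.6%) the change and total intron length had a Spearman rho of 0.23, 0.205 to 0.25 over omissions of 1 library, 0.208 without N40K replicate 1 and dTg replicate 2, and 0.106, 0.161, 0.206, 0.226 and 0.217 in 5 equal groups of genes from the lowest to the highest mean score. With genes in 5 groups by intron length, in the group with the least (median 3.07 kb) the median change was 0.01 and 3.7% of genes rose, and in the group with the most (median 133 kb) they were 0.13 and 17.1%. Of 100 splits of the libraries 3 gave a rho as large in size, under the share of 0.05 set beforehand. The highest other split gave 0.249, above the real 0.23, so chance is made less likely and is not excluded. The relation was not specific to N40K, with a rho of 0.111 for averaged 5xFAD and 0.151 for Tau P301S minus WT (12749 genes), and signal added along introns would give it too, so it does not separate a splicing effect from carried-over unspliced RNA or DNA.

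Zinc-finger genes (symbols Zfp with digits), to which Zfp930 belongs, made up 5 of the 147 genes lowered with N40K and 294 of all 15705 (odds ratio 1.86, 95% interval 0.59 to 4.49, Fisher's exact p = 0.204). The count is too small to decide whether they are over-represented, and after median-centring the odds ratio was 0.697 (7 of 528 genes).

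At 12 months the median score per library was 0.013 in WT replicates 1 and 2 and 0.017 in WT replicates 3 and 4, and lay between 0.014 and 0.016 in the 6 Tau P301S libraries. At 6 months 28 genes and at 12 months 66 genes had a score of 0 in all libraries, and the mean score was above 1 in 412 and 144 genes.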
